A study of Homo sapiens with 30 samples.

How the data were processed

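The series held 30 Detect-seq libraries of HEK293T cells, a transformed human embryonic kidney line. Detect-seq labels and pulls down DNA fragments that carry deoxyuridine, the product of cytosine deamination, and reads their positions across the genome. The cells carried DdCBEs, base editors in which the parts of a split bacterial double-stranded DNA deaminase (DddA) are each fused to a TALE array and sent to mitochondria. The arrays were aimed at mtDNA sites named ND4, ND5.1, ND5.3 and ND6. By the titles, the libraries formed 22 groups, 8 of 2 libraries and 14 of 1 library, with 27 pulldown and 3 input libraries. Among them were 24 libraries of the orientation labelled L1397N and 4 of L1397C. The 24 included 6 labelled Lipo2000, 3 with dead DddA, and 3 each in which the left or the right TALE array was left off and its DddA part stood alone, with MTS in the title. The remaining libraries were 1 with GFP and 1 with TALE-free DddA parts.

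The deposited files were 4 lists of regions, each the final list for 1 editor target, with no values per library. Per the submitters' processing notes, cutadapt, Bowtie2, SAMtools and Picard were used with the hg38 build, and their versions and roles are not given in the sources used here. How regions were called and chosen, and which libraries each list pools, is also not given in the sources used here. The lists for ND4, ND5.1 and ND6 carried a score, the signal value that the authors deposited for each region, per the file headers, with no stated normalization. They also carried a strand, an identifier with a class (IND, IND.Extend, DL or DR) and an interval in a further column. The ND5.3 list carried only chromosome, start and end. Whether coordinates count from 0 or from 1 is not stated, and starts and ends are printed as the authors gave them.

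Since each list is pooled, no error between replicates could be computed, and depth per library is unknown. Confidence intervals are 95% Wilson intervals over regions unless called exact, and cover counting error only. The signal value is the authors' own and was used to describe, rank and compare regions within a list, to compare the log2 difference between shared and list-specific regions across lists, and to correlate log2 values of regions that lists hold in common. Levels were not compared between lists.

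Regions that overlapped by at least 1 bp counted as shared. Overlap was tested against 10000 random placements of the shorter list, with chromosome and width kept, by a two-sided permutation test whose smallest possible p is 0.0002. Placements left out gene-free stretches over 2 Mb, which stood in for assembly gaps, since no genome sequence was used here. The share of regions held in another list was compared between lists with Fisher's exact test. Genes came from a RefSeq table on GRCh38.p14, the assembly that hg38 names, of which 58419 of 59792 genes lay on the 22 autosomes and X outside scaffolds and 19821 of those were protein-coding. The table gives gene bounds without strand or exons. The planned test of transcription start sites was therefore replaced by distance to the nearest gene end, meaning either bound of a gene, and exons, introns and UTRs were not analysed here. Signal values were compared between shared and list-specific regions as the difference of mean log2 values, with 100000 permutations, two-sided, and smallest possible p 1e-05. Differences between lists in that contrast used 10000 permutations of list labels, with smallest possible p 0.0001. Intervals of log2 differences came from 2000 bootstrap draws. P-values were adjusted by Benjamini-Hochberg within each family, with a threshold of 0.05.

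The tests were chosen before the data were examined, except those named as chosen afterwards or as not planned. The planned tests of GC content, CTCF motifs, mtDNA-like sequence, sequence like the editor's own target and placement matched on GC content need a genome sequence and could not be run. Named regions followed a rule set in advance. It took up to 12 regions found in 3 or 4 lists, those in most lists first and then by signal, up to 8 regions of highest signal per list, and up to 10 genes hit per fixed gene list. For ND5.3, which has no signal, the rule named 8 regions in coding exons or within 1 kb of a transcription start site. Without exons or strand, 8 regions near a protein-coding gene end were taken instead, shared ones first. Some regions that the rule names are not reported here. The rule did not say whose signal ranks shared regions, and that of ND6 was used. The 5 fixed gene lists held 212 genes, all with a position. Alternatives were other overlap and placement rules, the upper part of the signal, merged neighbours within 1 kb, other gene windows and class IND alone. No list names the libraries of dead DddA, GFP, TALE-free DddA parts, a missing TALE array, Lipo2000 or input, and they were not analysed here on their own.

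The procedures were tested on simulated data, with 200 runs of 300 regions each. Unrelated lists were called overlapping in 1% of runs, with midpoints within 500 bp, and 50 planted overlaps were called in 100% of runs. Random lists were called enriched at gene ends in 1.5% of runs, and lists with 30 planted gene-end regions in 100%. Equal signals were called different in 6% of runs, and a log2 difference of 0.5 over 100 regions in 97%. Computations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.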

Results

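Detect-seq was used to find deoxyuridine across the genome of HEK293T cells that carried mitochondrial base editors of the DdCBE type. The final lists for the ND4, ND5.1, ND5.3 and ND6 editors held 83, 539, 611 and 716 regions. All of them lay on the 22 autosomes and X, and no list held an mtDNA region. In the ND4, ND5.1 and ND6 lists the header of the identifier names off-targets. Regions in mtDNA may therefore have been left out when the lists were made. Their absence does not show that mtDNA was free of deoxyuridine. The regions were short, with median widths of 21, 19, 17 and 15 bp. Each list is pooled by the authors, so no value below has an error between replicates.

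The classes in the identifiers divided the lists unequally. Class IND made up 596 of 716 ND6 regions (83.2%), 333 of 539 ND5.1 regions (61.8%) and 36 of 83 ND4 regions (43.4%). Class IND.Extend held 167 ND5.1 and 35 ND4 regions and no ND6 region. Classes DL and DR held 91 and 29 ND6 regions, 13 and 26 ND5.1 regions, and 1 and 11 ND4 regions. The files do not define these names. Within a list, all regions of class DL had the same width, as did those of class DR (10 and 11 bp in ND6). Their interval never equalled the further interval, whereas that of classes IND and IND.Extend always did.

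The overlap of the lists addressed whether editors aimed at different mtDNA sites left marks in the same nuclear places. By the labels, the ND5.3 libraries were all of the L1397C orientation of DddA, those of ND5.1 and ND6 were all of L1397N and ND4 had both, so ND5.3 differed from ND5.1 and ND6 in orientation as well as in target. The 4 lists reduced to 1133 distinct regions, of which 512 (45.2%) were in at least 2 lists. ND5.3 and ND6 shared 489 regions, which was 80.0% of the ND5.3 list (95% interval 76.7 to 83.0) and 68.3% of the ND6 list (64.8 to 71.6). ND5.1 shared 284 regions with ND5.3 and 280 with ND6, or 52.7% (48.5 to 56.9) and 51.9% (47.7 to 56.1) of its list. ND4 shared 24 regions with ND5.1, 28 with ND5.3 and 25 with ND6, the last being 30.1% of its list (21.3 to 40.7). The largest combination was ND5.1, ND5.3 and ND6 with 248 regions, and 24 regions were in all 4 lists.

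Random placements gave at most 1 overlapping region in each of the 6 pairs, with means of 0.0008 to 0.0065. Every pair exceeded them (permutation test, adjusted p = 0.0002, the smallest the placements can give). All 1130 overlaps between lists had identical start and end, so the lists may draw on a common set of intervals. Separate placements would then be exceeded in any case, and the test cannot tell whether the editors acted at the same places. When lists were instead drawn at random from the 1133 distinct regions, ND5.3 and ND6 alone overlapped more than drawn, with 489 against 386.1 regions. That draw, chosen after seeing the data, overstates the expected overlap because places in none of the lists are missing from it. Its pool also holds classes IND.Extend, DL and DR, which were almost never shared. Drawn from the 768 distinct regions of class IND and ND5.3, further pairs overlapped more than drawn. These were ND4 with ND5.1 (24 against 15.6), ND5.1 with ND5.3 (283 against 264.9) and ND5.1 with ND6 (280 against 258.4). ND4 with ND5.3 and with ND6 did not differ from that draw.

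**Figure D1:**
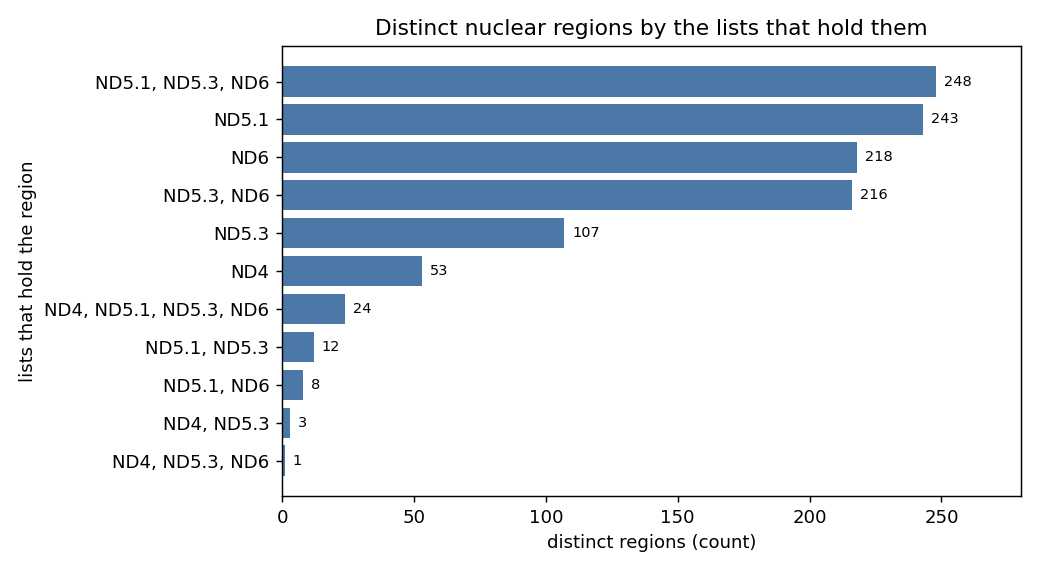
Bars give the number of distinct nuclear regions (x axis, count) for each combination of lists that holds them (y axis). The combination of ND5.1, ND5.3 and ND6 has 248 regions, the regions of ND5.1 alone number 243, and 24 regions are in all 4 lists.

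The regions in all 4 lists with the highest ND6 signal lay in or near genes of varied function. First was a region at chromosome 10, 119445511 to 119445546, inside GRK5, a kinase of G protein-coupled receptors, with the authors' signal value at 116.4 in ND6 (rank 1), 92.0 in ND5.1 (rank 3) and 5.303 in ND4 (rank 57). A region at chromosome 15, 68651256 to 68651277, lay inside CORO2B, a coronin family gene, and ranked 3 in ND6 and 5 in ND5.1. Regions inside AAK1, a kinase of clathrin-mediated endocytosis (chromosome 2, 69565500 to 69565533), BLOC1S3, a subunit of a lysosome biogenesis complex (chromosome 19, 45187694 to 45187712), and GPR161, an orphan receptor (chromosome 1, 168084921 to 168084945), ranked 8, 12 and 14 in ND6. Between genes, a region at chromosome 9, 98034893 to 98034930, lay 886 bp from TRIM14, and a region at chromosome 5, 69093805 to 69093830, lay 197 bp from SLC30A5, a zinc transporter. A region at chromosome 2, 201232409 to 201232430, lay 1044 bp from CASP8, the initiator caspase of death receptor signalling. The remaining 4 of these 12 regions were nearest to LOC105377136 (8495 bp), SMARCE1P4 (56972 bp), RPL5P21 (18211 bp) and ZBTB8A (18821 bp).

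The highest signals differed in kind between lists. In ND6, all 8 regions of highest signal were in other lists, and 6 of them were in all 4. They included a region inside STUM (chromosome 1, 226608903 to 226608925), which was in 3 lists at rank 2 in ND6 and rank 4 in ND5.1, and 1 inside the pseudogene TUBB4BP7 (chromosome 6, 152897977 to 152898014). In ND5.1, 7 of the 8 were shared, among them 1 inside SV2B, a synaptic vesicle gene (chromosome 15, 91247761 to 91247782). The exception was the ND5.1 region of highest signal, 148.6, of class IND.Extend inside GOLGB1, a Golgi protein gene (chromosome 3, 121749076 to 121749105). In ND4, 2 of the 8 were shared.

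The ND4 region of highest signal, 36.7, was of class DR inside TSHZ2, a zinc finger gene (chromosome 20, 53025824 to 53025841). Other ND4 regions in this group were of class IND.Extend 608 bp from PATE3 (chromosome 11, 125787502 to 125787536) and inside HCAR2, a receptor for hydroxylated fatty acids (chromosome 12, 122701468 to 122701505). The shared members were a region inside LAMA4-AS1, in 2 lists, and 1 that lay 3597 bp from RPS13P7, in all 4. Further ND4 members lay 17446 bp from GPR160P2 and 12694 bp from PHB1P3.

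For ND5.3, which had no signal, the regions chosen near protein-coding genes and held in all 4 lists were those near SLC30A5 and TRIM14, 1 that lay 310 bp from WASF1, an actin regulator (chromosome 6, 110179973 to 110179987), and 1 inside RAB5B, an early endosome GTPase (chromosome 12, 55996290 to 55996338). Those in 3 lists lay inside POLR3C, a subunit of RNA polymerase III (chromosome 1, 145824493 to 145824538), inside STUM, 336 bp from CIMIP5, and 70 bp from MLF1.

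Sharing followed class. In class IND, 28 of 36 ND4 regions (77.8%, 61.9 to 88.3), 291 of 333 ND5.1 regions (87.4%, 83.4 to 90.5) and 497 of 596 ND6 regions (83.4%, 80.2 to 86.2) were in another list. In class IND.Extend, 0 of 35 ND4 regions and 1 of 167 ND5.1 regions were. The difference between these classes passed Fisher's exact test in ND4 (adjusted p = 8.01e-13) and in ND5.1 (adjusted p = 1.42e-90). None of the 171 regions of classes DL and DR was shared, which allows a share of up to 1.75% by the limit of 3 regions for a count of 0, and up to 2.13% by the exact 95% interval. The comparison of classes was chosen after seeing the data. How classes were assigned is not known. If recurrence across editors entered into them, the test would set a label against its own definition, so it cannot tell why sharing differed.

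**Figure D2:**
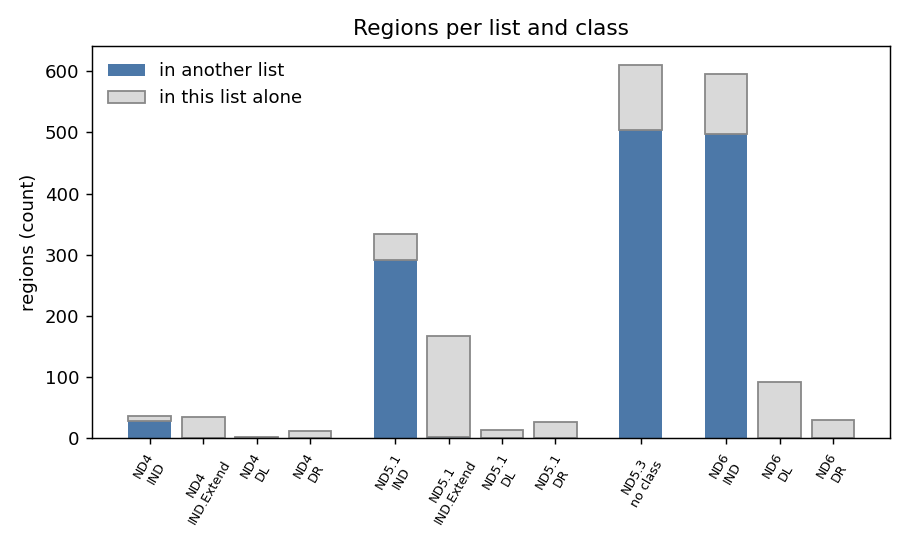
Stacked bars give regions (y axis, count) per list and class (x axis), split into regions found in another list and regions in that list alone. ND5.3 carries no class. In class IND most regions are shared, 497 of 596 in ND6, and none of classes DL and DR is.

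Whole lists differed in the share of regions found in another list. The share was 82.5% in ND5.3 (79.3 to 85.3), 69.4% in ND6 (65.9 to 72.7), 54.2% in ND5.1 (49.95 to 58.3) and 33.7% in ND4 (24.5 to 44.4). All 6 differences passed Fisher's exact test, with adjusted p from 9.96e-25 for ND5.1 against ND5.3 to 0.000584 for ND4 against ND5.1. Many shared regions stood in both lists of a pair, so the lists were not independent as the test assumes. With class IND alone, and ND5.3 whole, no pair passed Fisher's exact test, with adjusted p from 0.247 to 0.647, and the difference of ND5.3 minus ND5.1 was -5.06 percentage points.

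Gene annotation addressed where in the genome the regions fell. Regions lay within 1 kb of a gene end more often than placed at random in all 4 lists. The shares were 18.1% for ND4 (11.3 to 27.7), 19.3% for ND5.1 (16.2 to 22.8), 17.5% for ND5.3 (14.7 to 20.7) and 18.7% for ND6 (16.03 to 21.7), against 6.83%, 7.02%, 7.08% and 7.17% of placements. These are 2.65, 2.75, 2.47 and 2.61 times the placed shares, by permutation test with adjusted p = 0.0016 for ND4 and 0.000457 for the others. For protein-coding gene ends the ratios were 5.32, 4.48, 4.09 and 4.44 (permutation test, adjusted p = 0.000457 each). Without strand, starts and ends of genes could not be told apart.

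In contrast, gene bodies held 60.2% of ND4, 62.0% of ND5.1, 56.5% of ND5.3 and 57.4% of ND6 regions, against 59.8% to 60.2% of placements. No list passed the permutation test, with adjusted p from 0.139 to 1. For protein-coding gene bodies, ND5.1 alone passed, with 51.4% against 45.8% of placements, a ratio of 1.12 (permutation test, adjusted p = 0.0203). With placements kept 10 kb to 1 Mb from each region's own place, chosen after seeing the data, ND5.1, ND5.3 and ND6 regions lay in gene bodies less often, at 0.936, 0.870 and 0.882 times the placed share. In that setting the ND5.1 direction turned, as did that of ND4, at 0.924, which did not pass.

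**Figure D3:**
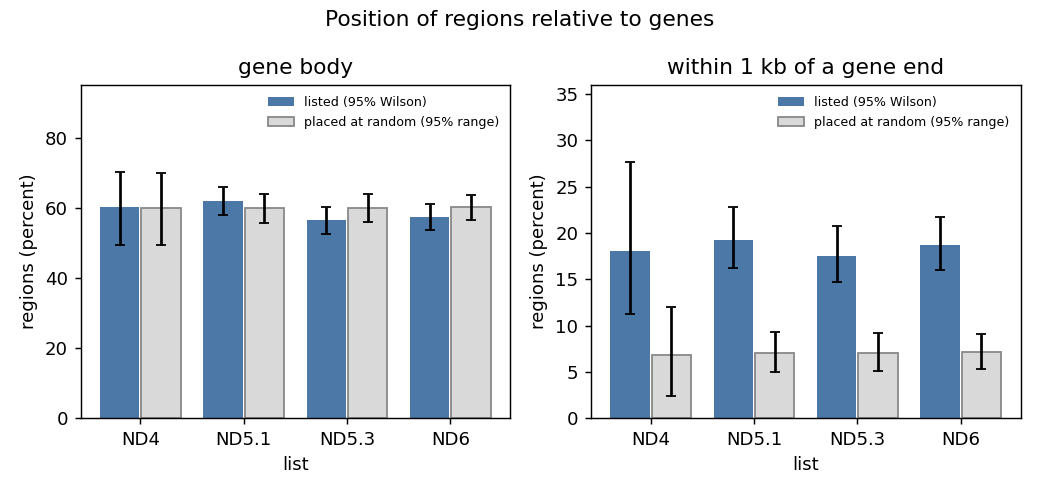
Bars give the share of regions (y axis, percent) in gene bodies (left) and within 1 kb of a gene end (right) per list (x axis), beside random placements. Error bars are 95% Wilson intervals for listed regions and 95% ranges for placements. The listed shares near gene ends, 17.5% to 19.3%, lie above the placed 6.83% to 7.17%.

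Shared and list-specific regions were compared by position. Over distinct regions, 286 of 512 shared regions (55.9%) and 400 of 621 list-specific regions (64.4%) lay in gene bodies, a difference of -8.55 percentage points (Fisher's exact test, adjusted p = 0.0408). Near gene ends the shares were 16.99% and 20.45%, a difference of -3.46 points that missed the threshold (Fisher's exact test, adjusted p = 0.295). An alternative required 2 other lists and counted the 239 regions in exactly 2 lists together with the list-specific ones. The gene-end difference was then 0.21 points. The gene body difference was also past the threshold in ND5.1 (56.8% against 68.0%, Fisher's exact test, adjusted p = 0.0487) and in no other list. With that alternative the gene body difference over distinct regions was -5.45 points and did not pass (Fisher's exact test, adjusted p = 0.501). Its comparison group differs, so it does not show a smaller difference from list-specific regions. Sharing differed by class, and in ND5.1 68.3% of class IND.Extend and 57.4% of class IND lay in gene bodies, a difference chosen after seeing the data that did not pass over 14 tests (Fisher's exact test, adjusted p = 0.138). Within class IND, with ND5.3 whole and chosen after seeing the data, the differences in gene bodies were -5.47 points over distinct regions (55.9% of 512 against 61.3% of 256) and -5.20 points in ND5.1, neither past the threshold (Fisher's exact test, adjusted p = 0.678 and 0.794).

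Signal values were compared within each list. In ND6, shared regions had a median of 11.97 and list-specific regions 6.45, a mean difference of 0.98 on the log2 scale (95% interval 0.87 to 1.09, n = 497 and 219, permutation test, adjusted p = 1.5e-05). In ND5.1 the medians were 12.6 and 9.50, with a log2 difference of 0.47 (0.33 to 0.62, n = 292 and 247, permutation test, adjusted p = 1.5e-05). In ND4 the medians were 5.46 and 7.72, with a log2 difference of -0.24 (-0.58 to 0.09, n = 28 and 55) that did not pass (permutation test, adjusted p = 0.198). Within class IND, chosen after seeing the data, the ND5.1 difference was 0.33 and missed the threshold (permutation test, adjusted p = 0.0533).

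Medians were also set out by the number of other lists, with no further test. In ND6 the median signal was 6.45 for regions in no other list, 8.54 with 1, 17.2 with 2 and 50.4 with 3 other lists. In ND5.1 the medians were 9.50, 7.75, 12.5 and 44.95, lower with 1 other list than with none. In ND4 it was 5.57 for the 24 regions in all lists against 7.72 for list-specific regions.

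**Figure D4:**
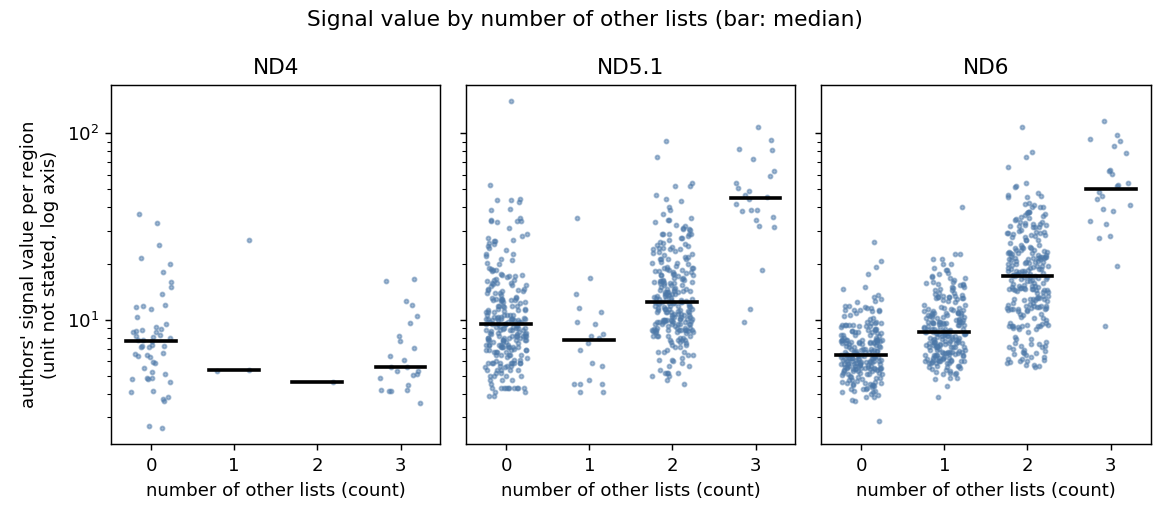
Each point is a region, with the authors' signal value on a log axis of unstated unit (y axis) against the number of other lists that hold it (x axis, count), for ND4, ND5.1 and ND6. Black bars are medians, and run from 6.45 to 50.4 in ND6. Levels are not comparable between panels.

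The fixed gene lists were hit rarely. Among the 76 genes of nuclear oxidative phosphorylation subunits, COX7A2, a cytochrome c oxidase subunit, held a region at chromosome 6, 75243922 to 75243932, in ND5.3 and ND6. Of 62 cancer genes, KEAP1, the sensor of oxidative stress (chromosome 19, 10492272 to 10492282, in ND5.3 and ND6), and NF2, which encodes merlin (chromosome 22, 29604068 to 29604086, in ND6), each held 1. The lists for mtDNA maintenance and expression (30 genes), uracil and base excision repair (25 genes) and chromatin architecture (20 genes) held none. No list differed from placements (permutation test, adjusted p = 1 for each), and with expected counts of at most 1.70 regions the test could hardly detect a shortage.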

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

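The tests of boundaries, of a calling limit and of class IND.Extend were chosen after the results were seen, as were the restriction to class IND and the draws of distinct regions. An earlier test of a calling limit, which carried signal values from ND6 to ND5.1, was replaced before it was run, because the values have no stated normalization.

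The contrast between shared and list-specific regions differed between lists. The plan compared signal within each list only, so this comparison between lists was not planned. The log2 difference was larger in ND6 than in ND4 by 1.22 and larger in ND6 than in ND5.1 by 0.50 (permutation of list labels, adjusted p = 0.00015 for each). It was larger in ND5.1 than in ND4 by 0.71 (permutation of list labels, adjusted p = 0.0015). Within class IND the difference of ND6 remained past the threshold against ND4 (1.21) and ND5.1 (0.68), and that of ND5.1 against ND4 (0.53) did not (permutation of list labels, adjusted p = 0.182). The ND4 side of class IND rested on 8 list-specific regions. The permutation treats values as independent, although 280 regions stood in both ND5.1 and ND6. Draws of distinct regions, each with its values in both lists, gave 95% intervals of 0.36 to 0.65 for ND6 against ND5.1, 0.87 to 1.56 for ND6 against ND4 and 0.33 to 1.07 for ND5.1 against ND4. Within class IND they gave 0.37 to 0.97, 0.70 to 1.78 and -0.05 to 1.12.

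The higher signal of shared regions in ND6 was set against region width. In 3 equal groups by width of class IND regions the log2 difference was 0.62, 1.06 and 1.26, with a mean of 0.98, which argues against width as the cause. A limit of calling in the other list stays open: the share of ND6 class IND regions also in ND5.1 went from 15% in the lowest of 5 equal parts of the signal to 94.96% (89.4 to 97.7) in the highest. The value passed the level set for the test, and the lower bound of its interval did not. The gradient had been seen before the test was chosen, so it is no independent evidence of a limit that weak regions fail to pass in ND5.1, and it is also consistent with strong sites being deaminated by every editor, which was not tested. ND4 showed no such difference, and no comparison with control libraries was possible here.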

How the results depend on the processing

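No paired analysis was possible because the lists are pooled and carry no value per replicate, although the labels share replicate numbers across groups. Alternatives using the further interval, class IND alone, nearby placements, 5 Mb gene-free stretches and draws from the distinct regions were chosen after seeing the data. Of 198 recomputed values, 156 kept their direction and side of the threshold, with counts within 1.5 times. All 6 overlaps kept theirs under whole-genome placement, placement within bins of distance to a gene end, merged neighbours, the further interval, class IND and nearby placement. Because all overlapping regions had identical boundaries, 50% reciprocal overlap could change no count and midpoints within 500 bp could lose none. The upper part of the signal left 42 ND4, 270 ND5.1 and 360 ND6 regions, fewer by construction. The overlaps were then 8, 9 and 8 for ND4 with ND5.1, ND5.3 and ND6. They were 175 and 164 for ND5.1 with ND5.3 and ND6, and 323 for ND5.3 with ND6. All stayed above placements. Against draws from the 1133 distinct regions, the counts of 24, 28, 25 and 280 (ND4 with ND5.1, ND5.3 and ND6, and ND5.1 with ND6) lay below the drawn 39.5, 44.8, 52.5 and 340.6, and the 284 of ND5.1 with ND5.3 lay below 290.7 without passing the threshold.

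With class IND alone the differences in shared percent were 9.61 points for ND5.1 minus ND4, 4.55 for ND5.3 minus ND4 and 5.61 for ND6 minus ND4, none past the threshold. They turned to -5.06 for ND5.3 minus ND5.1, -4.00 for ND6 minus ND5.1 and 1.07 for ND6 minus ND5.3, because the classes left out were almost never shared. For gene bodies, protein-coding genes alone gave a ratio of 1.12 in ND5.1, past the threshold. Nearby placement gave 0.936 in ND5.1, turned, 0.870 in ND5.3 and 0.882 in ND6, and for protein-coding bodies 0.960 in ND5.1, turned and not past the threshold, 0.838 in ND5.3 and 0.859 in ND6, newly past it. Nearby placement turned ND4 gene bodies to 0.924, and whole-genome placement turned ND6 protein-coding bodies to 1.01, neither past the threshold. Regions near gene ends kept their call in all 4 lists with 2 kb windows, protein-coding genes, whole-genome and nearby placement and 5 Mb stretches. Nearby placement lowered the ratios to 2.29 in ND4, 2.26 in ND5.1, 1.98 in ND5.3 and 2.09 in ND6. For protein-coding gene ends it lowered them to 3.88, 3.20, 2.92 and 3.18. Sharing with at least 2 other lists counted regions with 1 other list together with the list-specific ones. It gave -5.45 points in gene bodies over distinct regions and -11.5 in ND5.1, no longer past the threshold. It turned the gene-end differences, none past the threshold, to 2.78 points in ND5.3, 0.54 in ND6 and 0.21 over distinct regions. Because the comparison group changed, these values do not show a turned difference from list-specific regions. The causes were not tested. Class IND alone gave -5.47 points in gene bodies over distinct regions, no longer past the threshold, and turned gene-end ones to -3.57 in ND4 and 7.00 in ND5.1, neither past it. It gave 0.33 for the ND5.1 signal difference, with 42 list-specific regions in place of 247. No call of the fixed gene lists changed with 5 kb added on each side, though mtDNA maintenance and expression went from 0 regions to 2 in ND5.1 and 1 in ND6, above placements. Without a genome sequence, GC-matched placement, CTCF mismatches and windows, mtDNA-like sequence and target windows were not run.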

Other observations

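The tests of this part were all chosen after the data were seen.

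Regions held in common had the same strand and related signals in ND5.1 and ND6. All 280 regions had the same strand in both lists. Across those regions, which are not independent replicates, the log2 signals had Pearson's r of 0.79 and Spearman's rho of 0.74 (permutation test, adjusted over 6 correlations, p = 3e-05 for each). For the 24 regions of ND4 and ND5.1 rho was 0.35 and r 0.13, and for the 25 of ND4 and ND6 rho was 0.13 and r 0.07, none past the threshold (permutation test, adjusted p from 0.197 to 0.758). The strand was the same in 24 of 24 and 25 of 25. All these regions also had identical boundaries in both lists. If they came from a common set of intervals, the strand could agree by construction.

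Distinct regions were unevenly spread over chromosomes, by exact binomial tests on 23 chromosomes. The expected counts used placeable length alone, without gene density or the chromosome copy number of these cells. The tests therefore do not show a preference of the editors for chromosomes. Chromosome 1 held 148 against 90.4 by placeable length, chromosome 17 held 59 against 31.4, chromosome 22 held 30 against 14.98, chromosome 19 held 39 against 21.9 and chromosome 12 held 71 against 51.7 (exact binomial test, adjusted p = 1.11e-07, 8.1e-05, 0.00263, 0.00278 and 0.0237). Chromosome 2 held 58 against 95.4, chromosome 4 held 44 against 74.7, X held 39 against 60.03 and chromosome 18 held 17 against 29.7 (exact binomial test, adjusted p = 0.000174, 0.000553, 0.0139 and 0.039). Protein-coding genes with a region numbered 555, and 23 held at least 2 regions. MAGI1, a scaffold protein gene of 685.4 kb, held 3. In ND6, 27 of 91 class DL regions (29.7%) lay within 1 kb of a gene end against 17.8% of class IND, and 1 of 29 class DR regions (3.45%) did. Neither difference passed over 14 tests (Fisher's exact test, adjusted p = 0.138 and 0.153).

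All regions that overlapped between lists had the same start and end, 100% of 1130 pairs. The smallest overlap, 24 regions, lay above the highest of the placements, 1 region, which argues against overlap of separately and randomly placed regions. These placements kept only chromosome and width. They do not exclude chance overlap within a common set of intervals. Identical boundaries are consistent with boundaries taken from a common set of intervals, for instance calls made on several libraries together, which the sources used here do not describe. That explanation was found from these boundaries and stays open. No biological explanation was tested. When lists were drawn from the 768 distinct regions of class IND and ND5.3, 4 pairs exceeded the draws and ND4 with ND5.3 (28 against 28.6) and with ND6 (25 against 27.9) did not differ.

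Class IND.Extend was hardly shared, and a lower signal does not account for that. In ND4, where 0 of 35 were shared, its median signal was above that of class IND (7.77 against 5.57). In ND5.1, where it was below (9.47 against 12.5), class IND regions weighted to the signal of class IND.Extend were still shared at 85.9%, against 1 of 167 in class IND.Extend. In ND5.1 class IND.Extend lay on the minus strand in 63.5% of regions, 18.7 points above class IND (Fisher's exact test, adjusted p = 0.000256), and classes DL and DR in 100%. In ND4 the difference was 13.0 points (Fisher's exact test, adjusted p = 0.525). Class DR of ND4 lay on the minus strand in 11 of 11 regions (Fisher's exact test against class IND, adjusted p = 0.017), and its 1 region of class DL on the plus strand. In ND6 classes DL and DR were near balance at 51.6% and 48.3%. The strand had been seen before it was tested, so whether class IND.Extend resembles DL and DR stays open.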
